A study of Mus musculus with 30 samples.

How the data were processed

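Per the labels' protocols, 3T3-L1 cells were exposed from 2 days after confluence in medium with foetal bovine serum, and RNA of every sample was labelled with Cy3 and hybridised with a Cy5-labelled reference. Per the submitters' processing notes, the authors used limma, with no version given. The steps of background correction, normalization and probe filtering are not stated there. The deposited value of a probe is a log ratio of reference over sample. Its direction follows from the dyes given in the labels and from the authors' fold changes, and its base is not stated. It was read as log2, because the group differences had the size of the fold changes in the authors' deposited tables with the opposite sign, with a largest absolute sum of 5e-08. The authors' deposited tables give for each probe a fold change against DMSO, read as log2 as in limma's output, and an adjusted p-value, whose method of adjustment is not stated. The sign of the deposited ratios was turned so that positive values mean more RNA in the sample.

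Of the 23460 probes in the value table, 26 control probes were left out, and all probes of a gene were averaged. That gave 19231 gene or probe entries, of which 14763 were genes with a name and 4468 were probes without one. Gene symbols came from the probe table supplied with the data, which gave 18966 probes a symbol. A linear model with a mean for each of the 10 groups was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, followed by eBayes, with 20 residual and 3.56 prior degrees of freedom. All p-values of genes come from limma's moderated test, two-sided, adjusted by the method of Benjamini and Hochberg over all entries of a comparison. A gene was called changed at an adjusted p under 0.05. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, and again with a correlation estimated for each list, adjusted over the 33 lists of a comparison. There were 9 comparisons with DMSO and 3 direct ones (ROSI with MDI, TBT with ROSI and DEHP with BBP). Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

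The comparisons, the test, the threshold, 27 gene lists, 6 lists of cell type markers and 17 key genes were fixed before the data were examined, as was the rule for naming genes. That rule took up to 8 genes with the highest and 8 with the lowest fold change per agent among called genes whose arrays did not overlap, up to 6 each way in direct comparisons, the key genes, and up to 4 members of each list with the smallest p. Of the key genes, 15 were measured, and Cfd and Ucp1 were not. Lists held known adipocyte, lipid, mitochondrial, matrix, stress, receptor and cell type genes. Many lists share members, so their shifts are not separate results. Plin1 and Cidec stand among adipocyte markers, PPAR gamma targets and lipid droplet genes. Lpl and Nr1h3 stand among both PPAR gamma and LXR targets, and Angptl4 among PPAR gamma targets and the glucocorticoid response. Where 3 arrays are set against 3, an exact permutation test cannot give a p under 0.1. Groups of 3 arrays do not overlap by chance in 10% of genes, against 49.9% seen for MDI and 16.7% for DEHP. The agreement between agents expected from the shared controls alone was taken from 100 simulated draws.

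The fit was tested on simulated data with 200 of 19231 entries changed, 50 of each size. Each gene was given its residual SD over all 10 groups, the same in both runs. With the changes placed in MDI the fit called 56% of genes changed by 0.25 in the right direction. It called 88% at 0.5 and 98% at 1 and at 2, with 7 false calls (3.95% of the calls). In another draw, with the changes placed in DEHP, it called 54%, 96%, 100% and 100%, with 9 false calls (4.89%). A shift of 0.3 given to the cholesterol synthesis list in DEHP gave an adjusted p of 6.13e-59 in limma's camera, and 0 of the 32 other lists were called. The simulated genes were independent of each other, so this says nothing about false calls for lists whose members are correlated.

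The same counts were taken with each array centred on its median, with quantile normalization between arrays, with robust eBayes, with array weights, with the replicate number as a block, with only the compared groups in the fit, with each probe on its own, with a fold limit and without each replicate in turn. For PP against DMSO the replicate numbers paired in the data: after the group means were taken out, samples with the same number correlated best with each other (0.127, 0.207 and 0.166). Such a match can arise by chance with 3 samples, which was not tested. EB replicate 3 correlated at 0.24 with a DMSO sample of another number. Quantile normalization forces all arrays onto the same distribution, also where groups differ in spread. Smaller changes, lost calls and turned directions after it can thus come from that step itself. A filter on dim probes was not run, because intensities were not used here. The deposited table for DEHP was not used, because its numbers carry decimal commas and could not be checked by the same code. The 26 control probes gave 0 calls over the 9 comparisons with DMSO in limma, with fold changes between -0.19 and 0.15. They gave 27 results at unadjusted p under 0.05, a share above the 0.05 that would be reached without any difference.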

Results

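RNA levels were measured in 3T3-L1 cells, a mouse preadipocyte line that can be turned into fat cells in culture, on 30 arrays with 2 colours. Each array set the RNA of a single culture condition (Cy3) against a shared reference (Cy5), which per the labels was a mixture of equal parts of control and exposed samples. The 10 groups held 3 arrays each: the solvent control DMSO (0.1%), the hormonal cocktail MDI and the agents ROSI, TBT, BPA, BBP, DEHP, BP, EB and PP. MDI stands for isobutyl methylxanthine at 0.5 mM with dexamethasone at 0.25 µM and insulin at 10 µg/mL for 48 h, then insulin alone for 8 days. All cells were harvested on day 10. ROSI, TBT, BPA, BBP and DEHP are the usual abbreviations of rosiglitazone, tributyltin, bisphenol A, benzyl butyl phthalate and di(2-ethylhexyl) phthalate, which the labels do not spell out. BP, EB and PP are left as codes. No dose of these 8 agents is given in the labels.

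The number of arrays limits the precision. The medians of the 30 arrays lay between -0.00315 and 0.0138 once the deposited log ratios were turned to sample over reference. The base of the logs is not stated in the value table and is read as 2 throughout. The series record calls the 3 samples of a group biological replicates, but the labels do not say that they came from separate cultures, so the p-values measure only the spread between these samples. The deposited ratios, reference over sample, were turned to sample over reference. Before turning, the group differences were the negative of the fold changes in the authors' deposited tables (r = -1 across 23460 probes for each of 8 agents), so the signed values given here have the authors' direction. The group means of DMSO and MDI correlated at r = -0.488 across genes, and the direction was kept because the labels state the dyes. In the text, each gene is followed by its log2 fold change ± its SE from limma, with 3 arrays in each group, and 14763 named genes were tested in each comparison. That SE rests on a spread pooled over all 10 groups. For genes that vary more in DMSO it can be too small, as for Fabp4 (SD 0.37 in DMSO and 0.04 in ROSI).

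MDI was compared with DMSO to see what the standard route to fat cells changed. The gene that rose most was Cox7a1 (29.9-fold, 4.90 ± 0.10), a cytochrome oxidase subunit typical of muscle and brown fat, followed by Scd1 (29.4-fold, 4.88 ± 0.09, adjusted p = 3.65e-22), which makes monounsaturated fatty acids. The carbonic anhydrase Car3 (4.86 ± 0.13), the triglyceride enzyme Dgat2 (28-fold, 4.81 ± 0.09) and the haemoglobin scavenger Hp (4.79 ± 0.10) came next. Then came the insulin-responsive glucose transporter Slc2a4 (25-fold, 4.64 ± 0.08), the lipid carrier Fabp4 (4.58 ± 0.13) and the oxidase subunit Cox8b (4.55 ± 0.12). The adipogenic transcription factors Pparg (2.54 ± 0.06, adjusted p = 2.53e-20) and Cebpa (2.31 ± 0.09) rose, as did the adipokine Adipoq (4.23 ± 0.10) and the droplet coat protein Plin1 (3.60 ± 0.09). The fatty acid transporter Cd36 (4.18 ± 0.10), Pck1 (4.54 ± 0.10), Lpl (1.92 ± 0.06), Fasn (1.98 ± 0.09) and Angptl4 (1.53 ± 0.10) were higher too. Lower were the growth factor Tgfb3 (-1.92 ± 0.08, adjusted p = 2.86e-16), the lysozyme Lyz1 (-1.90 ± 0.09), the sodium pump subunit Atp1b1 (-1.90 ± 0.12) and smooth muscle actin Acta2 (-1.79 ± 0.08). The chemokines Ccl2 (-1.79 ± 0.09) and Ccl8 (-1.71 ± 0.08), the collagen Col8a1 (-1.78 ± 0.43) and the mineralisation inhibitor Mgp (-1.73 ± 0.14) fell as well. The preadipocyte gene Dlk1 (-0.47 ± 0.06) and the collagen gene Col1a1 (-0.41 ± 0.10) fell by less. Pdk4 (-0.17 ± 0.07), which limits glucose oxidation, did not pass, except without MDI replicate 2 (-0.21) or DMSO replicate 2 (-0.22).

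All 30 measured mature adipocyte markers rose in MDI (30 of 30 higher, 30 adjusted over the list alone, adjusted p = 5.29e-36), Retn (4.01 ± 0.08) among them. Oxidative phosphorylation was higher (57 of 57 higher, 57 adjusted over the list alone, adjusted p = 1.26e-42), with Cycs (2.68 ± 0.05) and Uqcrc2 (1.94 ± 0.05). The TCA cycle was higher (23 of 23 higher, 23 adjusted over the list alone, adjusted p = 9.69e-23), with Suclg1 (1.82 ± 0.06) and Sdhb (1.24 ± 0.03). Lipid droplet and lipolysis genes rose (20 of 21 higher, 20 adjusted over the list alone, adjusted p = 5.87e-21), with Cidec (4.43 ± 0.12) and Mgll (2.71 ± 0.08). PPAR gamma targets rose (24 of 27 higher, 24 adjusted over the list alone, adjusted p = 7.06e-20). Fatty acid synthesis rose (22 of 24 higher, 22 adjusted over the list alone, adjusted p = 1.04e-16), with Thrsp (3.67 ± 0.10) and Pcx (3.06 ± 0.11). Triglyceride synthesis rose (14 of 18 higher, 14 adjusted over the list alone, adjusted p = 2.9e-09), with Gpd1 (4.00 ± 0.13), and fatty acid oxidation as well (26 of 31 higher, 26 adjusted over the list alone, adjusted p = 5.32e-18). LXR targets were higher (11 of 14 higher, 11 adjusted over the list alone, adjusted p = 2.74e-09), with Nr1h3 (2.29 ± 0.08) and Apoc1 (3.93 ± 0.11). Cholesterol synthesis was higher (18 of 21 higher, 19 adjusted over the list alone, adjusted p = 8.37e-11), with Pmvk (2.28 ± 0.06) and Idi1 (1.27 ± 0.07). Adipogenic regulators were higher (14 of 23 higher, 14 adjusted over the list alone, adjusted p = 0.000426), with Klf15 (2.79 ± 0.07). Thermogenic genes were higher (11 of 14 higher, 11 adjusted over the list alone, adjusted p = 3.17e-07), with Cidea (2.49 ± 0.11). Insulin and glucose handling was higher (21 of 33 higher, 22 adjusted over the list alone, adjusted p = 3.25e-06), with Pygl (2.96 ± 0.07). The glucocorticoid response was higher (12 of 22 higher, 12 adjusted over the list alone, adjusted p = 0.0022), with Hsd11b1 (3.77 ± 0.05) and Glul (2.85 ± 0.09). That list shares Lpin1 with the adipogenic regulators and Angptl4 with the PPAR gamma targets, so its shift is not independent of theirs.

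Contractile and myofibroblast genes fell in MDI (17 of 22 lower, 17 adjusted over the list alone, adjusted p = 1.04e-08), with Myl9 (-1.03 ± 0.07) and Flna (-0.87 ± 0.07). Preadipocyte and anti-adipogenic genes were lower (19 of 29 lower, 20 adjusted over the list alone, adjusted p = 9.3e-07), with Ccn5 (-1.61 ± 0.07) and Id2 (-1.58 ± 0.12). Extracellular matrix genes were lower (25 of 41 lower, 26 adjusted over the list alone, adjusted p = 0.00013), with Fbln5 (-1.64 ± 0.08) and Eln (-0.85 ± 0.05). Inflammatory mediators such as Vcam1 (-0.66 ± 0.03) shifted down (13 of 29 lower, 15 adjusted over the list alone, adjusted p = 0.0187), although Hp rose. That list gave adjusted p = 0.094 with an estimated correlation. Ribosomal proteins such as Rps3 (-0.33 ± 0.04) shifted down (16 of 39 lower, 16 adjusted over the list alone, adjusted p = 0.00265) and gave adjusted p = 0.157 with an estimated correlation. No shift was found for cell cycle (7 of 41 higher and 6 lower, adjusted p = 0.939), interferon response (2 of 30 higher and 4 lower, adjusted p = 0.911) or retinoid response (6 of 17 higher and 5 lower, adjusted p = 0.392). None was found for aryl hydrocarbon receptor targets (3 of 8 higher and 2 lower, adjusted p = 0.834), the Nrf2 list (9 of 25 higher and 7 lower, adjusted p = 0.27) or endoplasmic reticulum stress (12 of 32 higher and 10 lower, adjusted p = 0.356). Heat shock (4 of 17 higher and 7 lower, adjusted p = 0.651) and oestrogen response (7 of 14 higher and 3 lower, adjusted p = 0.392) did not shift. Single members of those lists changed, such as Ccne1 (0.79 ± 0.05), Aldh1a7 (2.84 ± 0.09), Cyp1b1 (-0.75 ± 0.05), Cbr3 (1.53 ± 0.06) and Ero1a (1.63 ± 0.07). Markers of macrophages (0 of 11 higher and 3 lower, adjusted p = 0.656), endothelial cells (2 of 6 higher and 1 lower, adjusted p = 0.903) and skeletal muscle (1 of 8 higher and 2 lower, adjusted p = 0.512) did not shift. Neither did those of osteoblasts (1 of 8 higher and 3 lower, adjusted p = 0.617), chondrocytes (0 of 4 higher and 1 lower, adjusted p = 0.607) and epithelial cells (1 of 6 higher and 0 lower, adjusted p = 0.656). Over all genes, limma with Benjamini-Hochberg adjustment gave 6126 changed genes, 3228 higher and 2898 lower, of which 603 changed at least 2-fold. After quantile normalization 2525 were higher and 2713 lower. That step gives every array the same distribution and can even out such counts. The turned excess is therefore not read as a result.

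ROSI, an agonist of the nuclear receptor PPAR gamma, was compared with DMSO for the changes that follow activation of that receptor. Fabp3 (46.2-fold, 5.53 ± 0.18, adjusted p = 6.15e-18), a fatty acid carrier of muscle and brown fat, rose most, followed by Cox8b (4.92 ± 0.12), Cd36 (4.62 ± 0.10) and Fabp4 (4.58 ± 0.13). The interferon-inducible gene Ifi27l2a (4.47 ± 0.11), Pck1 (4.39 ± 0.10), the droplet protein Cidec (4.27 ± 0.12) and Arxes2 (4.00 ± 0.09) came next. Adipoq (3.55 ± 0.10), Plin1 (2.77 ± 0.09), Slc2a4 (2.87 ± 0.08), Scd1 (3.03 ± 0.09) and Lpl (1.40 ± 0.06) rose, as did Cebpa (1.51 ± 0.09), Pparg (1.15 ± 0.06, adjusted p = 1.77e-13) and Fasn (0.74 ± 0.09) (0.41 after quantile normalization). So did Pdk4 (1.62 ± 0.07, adjusted p = 1.42e-15) and the lipase inhibitor Angptl4 (1.64 ± 0.10), both known PPAR targets. The lowest genes included the Wnt modulator Sfrp2 (-1.26 ± 0.10), Acta2 (-1.21 ± 0.08) and the myosin light chain Myl9 (-1.20 ± 0.07). Tpbg (-1.32 ± 0.35) had the lowest value, but DMSO replicate 3 carried much of it, and without that array it was -0.59. The protease inhibitor Slpi (-1.19 ± 0.07), Atp1b1 (-1.18 ± 0.12), the pentraxin Ptx3 (-1.14 ± 0.07) and the matrix protease Mmp3 (-1.13 ± 0.12) followed. Dlk1 (-1.05 ± 0.06) and Col1a1 (-0.63 ± 0.10) fell.

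The mature adipocyte markers rose in ROSI (28 of 30 higher, 29 adjusted over the list alone, adjusted p = 7.29e-39). PPAR gamma targets rose (24 of 27 higher, 24 adjusted over the list alone, adjusted p = 6.5e-34). Oxidative phosphorylation rose (57 of 57 higher, 57 adjusted over the list alone, adjusted p = 1.3e-51), with Cycs (2.58 ± 0.05). Fatty acid oxidation rose (28 of 31 higher, 28 adjusted over the list alone, adjusted p = 2.4e-29), with Acaa2 (2.60 ± 0.05) and Hadhb (2.78 ± 0.09). Lipid droplet genes rose (19 of 21 higher, 19 adjusted over the list alone, adjusted p = 1.59e-22), with Plin4 (2.73 ± 0.06) and Ces1d (3.59 ± 0.10). Thermogenic genes rose (12 of 14 higher, 12 adjusted over the list alone, adjusted p = 3.68e-17), among them Cpt1b (1.88 ± 0.05) and Slc36a2 (2.91 ± 0.09). Cholesterol synthesis rose (19 of 21 higher, 20 adjusted over the list alone, adjusted p = 1.93e-18), with Pmvk (2.00 ± 0.06) and Nsdhl (1.17 ± 0.07). The TCA cycle, fatty acid and triglyceride synthesis, LXR targets, adipogenic regulators and insulin and glucose handling also shifted up with both settings of camera. Adipogenic regulators did not pass after quantile normalization (adjusted p = 0.0597). Cell cycle genes fell (31 of 41 lower, 32 adjusted over the list alone, adjusted p = 2.51e-15), among them Cdc20 (-0.71 ± 0.06), Hmgb2 (-0.68 ± 0.06) and Aurka (-0.49 ± 0.04). Contractile genes fell (16 of 22 lower, 18 adjusted over the list alone, adjusted p = 7.62e-10). Preadipocyte genes were lower (22 of 29 lower, 23 adjusted over the list alone, adjusted p = 1.19e-08), and extracellular matrix genes too (24 of 41 lower, 24 adjusted over the list alone, adjusted p = 2.52e-08), with Timp1 (-0.72 ± 0.07). Inflammatory mediators were lower (16 of 29 lower, 17 adjusted over the list alone, adjusted p = 1.07e-05), with Cx3cl1 (-1.02 ± 0.05). Ribosomal proteins shifted down (14 of 39 lower, 15 adjusted over the list alone, adjusted p = 0.0021) and gave adjusted p = 0.139 with an estimated correlation. In all, 4941 genes changed, 2648 higher and 2293 lower, and 389 at least 2-fold. After quantile normalization, which can even out such counts, 2324 were higher and 2522 lower.

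The direct contrast of ROSI with MDI asked which genes differed between the receptor agonist and the cocktail. Higher in ROSI were Fabp3 (33.5-fold, 5.07 ± 0.18, adjusted p = 1.48e-16), the chemokine Ccl8 (2.53 ± 0.08), the fatty acid elongase Elovl3 (1.94 ± 0.12) and Pdk4 (1.79 ± 0.07, adjusted p = 1.09e-15). The epoxide hydrolase Ephx2 (1.61 ± 0.10), the mitochondrial protein Chchd10 (1.49 ± 0.07), Cpt1b (0.96 ± 0.05) and Cd36 (0.44 ± 0.10) were also higher. Lower were Hp (-3.36 ± 0.10, adjusted p = 1.08e-17), Selenbp1 (-3.30 ± 0.11), the antimicrobial peptide gene Camp (-3.23 ± 0.10) and the folate enzyme Aldh1l1 (-3.15 ± 0.13). Wfdc21 (-3.10 ± 0.09), the adipokine Retn (-2.91 ± 0.08), Slc2a4 (-1.77 ± 0.08), Scd1 (-1.85 ± 0.09) and Fasn (-1.24 ± 0.09) were lower in ROSI. So were Pparg (-1.39 ± 0.06), Cebpa (-0.80 ± 0.09), Plin1 (-0.83 ± 0.09), Dlk1 (-0.57 ± 0.06) and Lpl (-0.52 ± 0.06) (-0.18 after quantile normalization). Adipoq (-0.68 ± 0.10) was lower, but its call ended after that step (-0.26). Fabp4 (0.00 ± 0.13), Pck1 (-0.15 ± 0.10) and Angptl4 (0.11 ± 0.10) did not pass.

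Cell cycle genes lay lower in ROSI than in MDI (31 of 41 lower, 33 adjusted over the list alone, adjusted p = 1.08e-20), with Ube2c (-0.85 ± 0.05) and Ccne1 (-0.75 ± 0.05). Glucocorticoid response genes were lower (13 of 22 lower, 14 adjusted over the list alone, adjusted p = 4.76e-07), with Hsd11b1 (-2.58 ± 0.05) and Glul (-1.63 ± 0.09). Adipogenic regulators were lower (14 of 23 lower, 14 adjusted over the list alone, adjusted p = 5.38e-06), with Klf15 (-2.22 ± 0.07). Insulin and glucose handling shifted down (15 of 33 lower, 17 adjusted over the list alone, adjusted p = 1.03e-06), with Pygl (-2.59 ± 0.07). LXR targets were lower (9 of 14 lower, 9 adjusted over the list alone, adjusted p = 6.18e-07), with Apoc1 (-2.14 ± 0.11) and Apoe (-0.90 ± 0.09). Other shifts did not pass with an estimated correlation. Mature adipocyte markers (17 of 30 lower, 17 adjusted over the list alone, adjusted p = 5.26e-09) gave adjusted p = 0.115 with an estimated correlation. Fatty acid synthesis (17 of 24 lower, 18 adjusted over the list alone, adjusted p = 1.78e-06) gave adjusted p = 0.11 with an estimated correlation. Thermogenic genes (7 of 14 higher, 9 adjusted over the list alone, adjusted p = 4.86e-06) gave adjusted p = 0.11 with an estimated correlation. Cholesterol synthesis (7 of 21 higher, 7 adjusted over the list alone, adjusted p = 0.0128) gave adjusted p = 0.205 with an estimated correlation. Fatty acid oxidation (12 of 31 higher, 15 adjusted over the list alone, adjusted p = 0.0147) gave adjusted p = 0.271 with an estimated correlation. Endoplasmic reticulum stress (12 of 32 lower, 13 adjusted over the list alone, adjusted p = 0.0426), with Ero1a (-1.27 ± 0.07) and Xbp1 (-1.02 ± 0.09), gave adjusted p = 0.158 with an estimated correlation. Lipid droplet genes (11 of 21 lower, 11 adjusted over the list alone, adjusted p = 0.00425) gave adjusted p = 0.236 with an estimated correlation, and their median of -0.41 turned to 0.0095 after quantile normalization. The TCA cycle (11 of 23 lower, 12 adjusted over the list alone, adjusted p = 0.00484) gave adjusted p = 0.205 with an estimated correlation, and its median of -0.15 turned to 0.047. Oxidative phosphorylation (16 of 57 lower, 18 adjusted over the list alone, adjusted p = 9.24e-06) gave adjusted p = 0.205 with an estimated correlation, and its median of -0.12 turned to 0.047. The contrast gave 3332 changed genes, 1604 higher and 1728 lower, of which 136 changed at least 2-fold. Quantile normalization, which can even out such counts, gave 1170 higher and 1057 lower genes (2227 in all).

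TBT, a ligand of the receptors PPAR gamma and RXR, was compared with DMSO for its adipogenic changes. The genes that rose most were Fabp3 (23.3-fold, 4.54 ± 0.18, adjusted p = 8.03e-16), Cox8b (3.81 ± 0.12), Scd1 (3.77 ± 0.09) and Cox7a1 (3.74 ± 0.10), followed by Ifi27l2a (3.58 ± 0.11), Cd36 (3.51 ± 0.10), Prxl2a (3.40 ± 0.09) and Fabp4 (3.40 ± 0.13). Pparg (0.98 ± 0.06), Cebpa (1.01 ± 0.09), Adipoq (2.21 ± 0.10), Plin1 (2.27 ± 0.09) and Pck1 (2.92 ± 0.10) rose. Lpl (1.11 ± 0.06), Slc2a4 (2.28 ± 0.08), Fasn (0.88 ± 0.09), Pdk4 (1.68 ± 0.07) and Angptl4 (2.20 ± 0.10, adjusted p = 7.33e-15) rose too. Lower were Slpi (-1.94 ± 0.07, adjusted p = 3.29e-16), the secreted peptide gene Ecrg4 (-1.55 ± 0.09), Sfrp2 (-1.40 ± 0.10), the chaperone Clu (-1.28 ± 0.05) and the matrix protein Dpt (-1.27 ± 0.09). The cytokine Il33 (-1.21 ± 0.11), Atp1b1 (-1.19 ± 0.12), Ptx3 (-1.18 ± 0.07), Dlk1 (-0.97 ± 0.06) and Col1a1 (-0.37 ± 0.10) fell as well.

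Interferon response genes rose in TBT (20 of 30 higher, 22 adjusted over the list alone, adjusted p = 6.21e-08), with Gbp2 (0.84 ± 0.08), Irgm1 (0.71 ± 0.12), Isg15 (1.16 ± 0.21) and Ifi27 (0.71 ± 0.10). The list gave adjusted p = 0.187 with an estimated correlation, its members being correlated (0.506). LXR targets rose (11 of 14 higher, 11 adjusted over the list alone, adjusted p = 4.43e-15), with Nr1h3 (1.95 ± 0.08) and Apoc1 (2.77 ± 0.11). The retinoid response shifted up (7 of 17 higher, 7 adjusted over the list alone, adjusted p = 0.0153), with the retinoic acid hydroxylase Cyp26b1 (2.40 ± 0.09) and Fabp5 (1.82 ± 0.09), although the median of that list was -0.01. Its call ended after quantile normalization (adjusted p = 0.102). The Nrf2 list (10 of 25 higher, 10 adjusted over the list alone, adjusted p = 0.0133), with Cbr3 (1.67 ± 0.06), gave adjusted p = 0.0554 with an estimated correlation. The glucocorticoid response (8 of 22 higher, 10 adjusted over the list alone, adjusted p = 0.0364) gave adjusted p = 0.114 with an estimated correlation, and its call also ended without TBT replicate 1 (adjusted p = 0.0505) or DMSO replicate 3 (0.0668) and after quantile normalization (0.687). Mature adipocyte markers rose (28 of 30 higher, 28 adjusted over the list alone, adjusted p = 3.08e-43). PPAR gamma targets were higher (25 of 27 higher, 25 adjusted over the list alone, adjusted p = 1.41e-37), and oxidative phosphorylation too (57 of 57 higher, 57 adjusted over the list alone, adjusted p = 7.04e-47). The TCA cycle, fatty acid oxidation, lipid droplet genes, fatty acid, triglyceride and cholesterol synthesis, thermogenic genes, insulin and glucose handling and adipogenic regulators also shifted up with both settings of camera. Adipogenic regulators lost the call after quantile normalization (adjusted p = 0.0886). Preadipocyte genes were lower (16 of 29 lower, 18 adjusted over the list alone, adjusted p = 5.88e-08), with Thy1 (-0.78 ± 0.07). Extracellular matrix genes shifted down (20 of 41 lower, 21 adjusted over the list alone, adjusted p = 3.68e-06), with Lum (-1.03 ± 0.09). Contractile genes were lower (12 of 22 lower, 14 adjusted over the list alone, adjusted p = 4.63e-05), with Cdh2 (-0.65 ± 0.09). Inflammatory mediators shifted down (14 of 29 lower, 15 adjusted over the list alone, adjusted p = 0.000337). Ribosomal proteins (9 of 39 lower, 9 adjusted over the list alone, adjusted p = 0.00141) gave adjusted p = 0.117 with an estimated correlation. TBT changed 3958 genes, 2225 higher and 1733 lower, and 217 at least 2-fold. With quantile normalization, which can even out such counts, 1990 were higher and 2059 lower.

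Set directly against ROSI, TBT raised the apolipoprotein genes Apoc2 (3.57-fold, 1.83 ± 0.07, adjusted p = 9.42e-15), Apod (1.67 ± 0.11) and Apoe (1.44 ± 0.09, adjusted p = 1.13e-11). Cyp26b1 (1.76 ± 0.09), the interferon-inducible genes Rtp4 (1.49 ± 0.29) and Oasl2 (1.44 ± 0.24), Scd1 (0.75 ± 0.09) and Angptl4 (0.55 ± 0.10) were also higher in TBT. Lower in TBT were Elovl3 (-1.86 ± 0.12, adjusted p = 3.64e-11), the retinal dehydrogenase homologue Aldh1a7 (-1.80 ± 0.09), Pck1 (-1.47 ± 0.10), Rgs17 (-1.42 ± 0.08) and the scavenger receptor Olr1 (-1.40 ± 0.07). Adipoq (-1.35 ± 0.10), Fabp4 (-1.18 ± 0.13), Cd36 (-1.11 ± 0.10) and Cebpa (-0.50 ± 0.09) were lower, as were Plin1 (-0.50 ± 0.09), Slc2a4 (-0.59 ± 0.08) and Lpl (-0.29 ± 0.06). Pdk4 (0.06 ± 0.07), Fasn (0.14 ± 0.09) and Dlk1 (0.08 ± 0.06) did not pass.

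Cell cycle genes lay higher in TBT than in ROSI (30 of 41 higher, 30 adjusted over the list alone, adjusted p = 2.14e-25), with Plk1 (0.63 ± 0.05) and Cdc20 (0.67 ± 0.06). Contractile genes shifted up (9 of 22 higher, 10 adjusted over the list alone, adjusted p = 1.66e-07), with Tpm2 (0.66 ± 0.04). The interferon response (21 of 30 higher, 25 adjusted over the list alone, adjusted p = 1.09e-15), with Psmb8 (0.63 ± 0.09) and Bst2 (1.03 ± 0.15), gave adjusted p = 0.0759 with an estimated correlation. LXR targets (6 of 14 higher, 6 adjusted over the list alone, adjusted p = 0.00282), with Abca1 (0.86 ± 0.11), gave adjusted p = 0.122 with an estimated correlation. Extracellular matrix genes (11 of 41 higher, 14 adjusted over the list alone, adjusted p = 0.0143) gave adjusted p = 0.0759 with an estimated correlation. Oxidative phosphorylation was lower (46 of 57 lower, 50 adjusted over the list alone, adjusted p = 2.25e-30), with Ndufb5 (-0.46 ± 0.04). Mature adipocyte markers were lower (22 of 30 lower, 22 adjusted over the list alone, adjusted p = 3.84e-13). Lipid droplet genes were lower (14 of 21 lower, 17 adjusted over the list alone, adjusted p = 8.73e-13), with Plin4 (-1.23 ± 0.06). Fatty acid oxidation was lower (20 of 31 lower, 23 adjusted over the list alone, adjusted p = 1.32e-10), with Cpt1b (-1.24 ± 0.05). Cholesterol synthesis was lower (14 of 21 lower, 14 adjusted over the list alone, adjusted p = 8.73e-11), with Insig1 (-0.63 ± 0.08). The TCA cycle, PPAR gamma targets and thermogenic genes also shifted down with both settings of camera. The contrast gave 2880 changed genes, 1139 higher and 1741 lower, against 1288 and 1675 after quantile normalization, and 43 changed at least 2-fold.

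BPA was compared with DMSO as a candidate obesogen. The adipocyte genes Fabp4 (4.85-fold, 2.28 ± 0.13, adjusted p = 3.63e-12), Plin1 (2.20 ± 0.09), Cd36 (2.02 ± 0.10) and Adipoq (1.88 ± 0.10) rose most. The receptor accessory gene Mrap (1.87 ± 0.11), Prxl2a (1.82 ± 0.09), Cidec (1.81 ± 0.12) and the glycerol phosphate dehydrogenase Gpd1 (1.69 ± 0.13) came next. Pparg (1.07 ± 0.06), Cebpa (0.91 ± 0.09), Lpl (0.87 ± 0.06) and Pck1 (1.55 ± 0.10) rose. Slc2a4 (1.43 ± 0.08), Scd1 (1.40 ± 0.09) and Angptl4 (0.75 ± 0.10) rose too, but their calls ended after quantile normalization (0.18, 0.15 and 0.24). Fasn (0.25 ± 0.09, adjusted p = 4.63e-02) passed narrowly, but turned down after quantile normalization (-0.11), and its call ended without BPA replicate 2 or 3 or DMSO replicate 1 or 2. Pdk4 (-0.26 ± 0.07, adjusted p = 1.06e-02) was lower (-0.45 after quantile normalization), but its call ended without DMSO replicate 1 (-0.22). The matrix genes Mfap4 (-1.94 ± 0.10, adjusted p = 2.30e-12), Dpt (-1.47 ± 0.09) and Mmp3 (-1.30 ± 0.12) fell, as did Ecrg4 (-1.65 ± 0.09). The secretory kinase homologue Fam20a (-1.16 ± 0.05), Fxyd5 (-1.13 ± 0.07), Myl9 (-1.15 ± 0.07) and Acta2 (-1.13 ± 0.08) were lower. Dlk1 (-0.36 ± 0.06) and Col1a1 (-0.53 ± 0.10) fell by less.

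Mature adipocyte markers were higher in BPA (27 of 30 higher, 27 adjusted over the list alone, adjusted p = 6.17e-37). PPAR gamma targets were higher (19 of 27 higher, 20 adjusted over the list alone, adjusted p = 3.01e-20), with Pex11a (1.21 ± 0.07). Oxidative phosphorylation was higher (49 of 57 higher, 51 adjusted over the list alone, adjusted p = 1.09e-27), with Uqcrc2 (0.77 ± 0.05). Lipid droplet genes rose (14 of 21 higher, 15 adjusted over the list alone, adjusted p = 1.62e-16), with Plin4 (1.04 ± 0.06). Triglyceride synthesis rose (9 of 18 higher, 9 adjusted over the list alone, adjusted p = 4.84e-06), with Gpat3 (1.40 ± 0.08). The TCA cycle, fatty acid oxidation, LXR targets, fatty acid and cholesterol synthesis and adipogenic regulators also shifted up with both settings of camera. The adipogenic regulators did not pass after quantile normalization (adjusted p = 0.0638). Thermogenic genes were higher (8 of 14 higher, 8 adjusted over the list alone, adjusted p = 1.46e-06), with a median of 0.31 that turned to -0.0077 after quantile normalization, where the call ended (adjusted p = 0.911). Contractile genes were lower (14 of 22 lower, 14 adjusted over the list alone, adjusted p = 6.47e-11), with Cnn2 (-0.69 ± 0.08). Extracellular matrix genes shifted down (18 of 41 lower, 21 adjusted over the list alone, adjusted p = 7.75e-09), with Fbln5 (-1.08 ± 0.08). Preadipocyte genes shifted down (8 of 29 lower, 8 adjusted over the list alone, adjusted p = 5.62e-05), with Ccn5 (-1.11 ± 0.07). Inflammatory mediators shifted down (10 of 29 lower, 12 adjusted over the list alone, adjusted p = 0.00285), with Ccl7 (-0.79 ± 0.08) and Il33 (-1.07 ± 0.11). The cell cycle list (10 of 41 higher, 13 adjusted over the list alone, adjusted p = 0.00209), with Cdca3 (0.40 ± 0.05), gave adjusted p = 0.157 with an estimated correlation. Insulin and glucose handling (10 of 33 higher, 11 adjusted over the list alone, adjusted p = 0.00749) gave adjusted p = 0.0909 with an estimated correlation and 0.28 after quantile normalization. The interferon response (4 of 30 higher and 0 lower, adjusted p = 0.034) shifted up and gave adjusted p = 0.594 with an estimated correlation. That call also ended without BPA replicate 1 (adjusted p = 0.265) or DMSO replicate 2 (0.0883). BPA changed 3031 genes, 1856 higher and 1175 lower, against 1135 higher and 1211 lower after quantile normalization. Of the 3031, 74 changed at least 2-fold.

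BBP and DEHP are both diesters of phthalic acid and were each compared with DMSO and then with each other. BBP raised Fabp4 (6.13-fold, 2.62 ± 0.13, adjusted p = 1.95e-13), Cox8b (2.61 ± 0.12), Scd1 (2.52 ± 0.09), Ifi27l2a (2.48 ± 0.11) and the lipogenic gene Thrsp (2.33 ± 0.10). Adipoq (2.31 ± 0.10), the carboxylesterase Ces1d (2.27 ± 0.10), Mrap (2.16 ± 0.11), Cd36 (2.12 ± 0.10) and Pck1 (2.07 ± 0.10) rose as well. Plin1 (1.77 ± 0.09), Pparg (0.86 ± 0.06), Cebpa (0.94 ± 0.09), Lpl (0.68 ± 0.06) and Fasn (0.62 ± 0.09) rose by less. The call of Slc2a4 (1.68 ± 0.08) ended after quantile normalization (0.16). Lower were the immediate early genes Nr4a1 (-0.84 ± 0.06, adjusted p = 8.88e-11) and Egr1 (-0.58 ± 0.10), the transcription regulators Klf4 (-0.73 ± 0.11) and Id2 (-0.60 ± 0.12), Ecrg4 (-0.69 ± 0.09) and Slpi (-0.52 ± 0.07). Pdk4 (-0.09 ± 0.07), Dlk1 (-0.08 ± 0.06) and Col1a1 (-0.25 ± 0.10) did not pass.

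Mature adipocyte markers were higher in BBP (27 of 30 higher, 28 adjusted over the list alone, adjusted p = 2.72e-65). Oxidative phosphorylation was higher (39 of 57 higher, 49 adjusted over the list alone, adjusted p = 5.74e-34), with Cyc1 (0.85 ± 0.06). PPAR gamma targets were higher (19 of 27 higher, 21 adjusted over the list alone, adjusted p = 9.88e-31). The TCA cycle rose (19 of 23 higher, 19 adjusted over the list alone, adjusted p = 1.12e-25), with Pdhb (0.79 ± 0.08). Cholesterol synthesis rose (18 of 21 higher, 19 adjusted over the list alone, adjusted p = 1.2e-23), with Idi1 (0.73 ± 0.07) and Tm7sf2 (0.59 ± 0.06). Lipid droplet genes, fatty acid synthesis and oxidation, LXR targets, triglyceride synthesis, insulin and glucose handling and adipogenic regulators also shifted up with both settings of camera. After quantile normalization insulin and glucose handling (adjusted p = 0.515) and adipogenic regulators (0.183) did not pass. Thermogenic genes were higher (8 of 14 higher, 8 adjusted over the list alone, adjusted p = 2.41e-10), with a median of 0.33 that turned to -0.018 after quantile normalization, where the call ended (adjusted p = 0.515). Preadipocyte genes shifted down as a list (9 of 29 lower, 13 adjusted over the list alone, adjusted p = 1.33e-06). So did contractile genes, of which few passed singly (2 of 22 lower, 3 adjusted over the list alone, adjusted p = 0.00317). Inflammatory mediators shifted down (5 of 29 lower, 6 adjusted over the list alone, adjusted p = 0.00314), with Il6 (-0.39 ± 0.06). Extracellular matrix genes (4 of 41 lower, 5 adjusted over the list alone, adjusted p = 0.0217) gave adjusted p = 0.0784 with an estimated correlation, and the call ended without DMSO replicate 3 (adjusted p = 0.0798). Ribosomal proteins (3 of 39 lower, 3 adjusted over the list alone, adjusted p = 0.000463) gave adjusted p = 0.0925 with an estimated correlation. BBP changed 1460 genes, 1093 higher and 367 lower, against 511 and 436 after quantile normalization, and 58 changed at least 2-fold. The count was 969 without BBP replicate 3 and 814 without DMSO replicate 2.

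DEHP left nearly all genes short of the threshold. The immediate early gene Nr4a1 (-0.43 ± 0.06, adjusted p = 1.63e-03) was lower and the adaptor gene Lims1 (0.30 ± 0.05, adjusted p = 1.85e-02) higher. The call of Lims1 ended without DEHP replicate 1, 2 or 3 and without DMSO replicate 2. These 2 were the only genes limma called, with 1676 at unadjusted p under 0.05. The count was 4 without DEHP replicate 1 and 1 without DEHP replicate 3. It was 5 without DMSO replicate 1, 1 without DMSO replicate 2 and 37 without DMSO replicate 3. After quantile normalization 3 genes were higher and 8 lower. Fabp4 (0.30 ± 0.13), Adipoq (0.12 ± 0.10), Plin1 (0.13 ± 0.09) and Cd36 (0.15 ± 0.10) did not pass. Pparg (0.10 ± 0.06), Cebpa (0.02 ± 0.09) and Slc2a4 (0.03 ± 0.08) did not pass either. Cholesterol synthesis was the list that shifted up with both settings of camera (0 of 21 higher, 10 adjusted over the list alone, adjusted p = 1.15e-11), with adjusted p = 0.00429 with an estimated correlation. Its members Msmo1 (0.33 ± 0.07), Nsdhl (0.31 ± 0.07) and Idi1 (0.25 ± 0.07) did not pass singly. The cell cycle list (0 of 41 higher and 0 lower, adjusted p = 2.38e-05) shifted down and gave adjusted p = 0.312 with an estimated correlation. Fatty acid synthesis (0 of 24 higher and 0 lower, adjusted p = 0.0393) shifted up and gave adjusted p = 0.479 with an estimated correlation. Mature adipocyte markers (0 of 30 higher and 0 lower, adjusted p = 0.024) shifted up, with a median of 0.10 that turned to -0.024 after quantile normalization. That list gave adjusted p = 0.57 with an estimated correlation. The calls of the adipocyte markers and of fatty acid synthesis ended after quantile normalization, without DEHP replicate 2 or 3 and without DMSO replicate 2, where the adipocyte markers pointed down (adjusted p = 0.839).

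Between the phthalate diesters, Cox8b (-2.45 ± 0.12, adjusted p = 2.86e-13), Ifi27l2a (-2.42 ± 0.11), Fabp4 (-2.31 ± 0.13), Scd1 (-2.24 ± 0.09) and Adipoq (-2.19 ± 0.10, adjusted p = 1.34e-13) were lower in DEHP than in BBP. Thrsp (-2.18 ± 0.10), Cd36 (-1.97 ± 0.10), Pck1 (-1.90 ± 0.10), Plin1 (-1.64 ± 0.09) and Cebpa (-0.92 ± 0.09) were lower too. So were Pparg (-0.76 ± 0.06), Lpl (-0.57 ± 0.06), Slc2a4 (-1.65 ± 0.08) and Fasn (-0.49 ± 0.09), whose calls ended after quantile normalization (-0.21, -0.14, -0.24 and -0.21). Higher in DEHP were Egr1 (0.92 ± 0.10, adjusted p = 6.19e-07), Fam13b (0.60 ± 0.11), the matricellular gene Ccn1 (0.59 ± 0.12), Slpi (0.58 ± 0.07) and Ecrg4 (0.55 ± 0.09). Mature adipocyte markers were lower in DEHP (27 of 30 lower, 28 adjusted over the list alone, adjusted p = 2.48e-76). PPAR gamma targets were lower (17 of 27 lower, 21 adjusted over the list alone, adjusted p = 6.14e-37). Lipid droplet genes were lower (16 of 21 lower, 19 adjusted over the list alone, adjusted p = 2.28e-31), with Ces1d (-2.04 ± 0.10). Oxidative phosphorylation was lower (45 of 57 lower, 53 adjusted over the list alone, adjusted p = 4.13e-47). Fatty acid synthesis was lower (14 of 24 lower, 20 adjusted over the list alone, adjusted p = 1.6e-20). The TCA cycle, fatty acid oxidation, triglyceride and cholesterol synthesis, LXR targets and adipogenic regulators also shifted down with both settings of camera. Insulin and glucose handling shifted down (5 of 33 lower, 8 adjusted over the list alone, adjusted p = 0.000744), with a median of -0.078 that turned to 0.0032 after quantile normalization. The retinoid response shifted down (6 of 17 lower, 6 adjusted over the list alone, adjusted p = 0.0146), with a median of -0.041 that turned to 0.0081 after it. Thermogenic genes fell (7 of 14 lower, 8 adjusted over the list alone, adjusted p = 8.37e-10), with a median of -0.31 that turned to 0.044 after it. Some lists shifted up while few of their members passed singly: preadipocyte genes (2 of 29 higher, 8 adjusted over the list alone, adjusted p = 2.58e-06) and extracellular matrix genes (1 of 41 higher, 3 adjusted over the list alone, adjusted p = 1.29e-05). Contractile genes shifted up in the same way (3 of 22 higher, 5 adjusted over the list alone, adjusted p = 0.00171). The Nrf2 list (4 of 25 lower, 5 adjusted over the list alone, adjusted p = 0.0139) gave adjusted p = 0.058 with an estimated correlation. Ribosomal proteins (1 of 39 higher, 0 adjusted over the list alone, adjusted p = 0.000391) gave adjusted p = 0.0836 with an estimated correlation. The contrast gave 928 changed genes, 157 higher and 771 lower, against 149 and 319 after quantile normalization. The count was 595 without BBP replicate 3. Of the 928, 42 changed at least 2-fold. Doses are not in the labels, so the contrast is of these cultures as treated.

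BP was compared with DMSO under its code. The adipocyte genes Fabp4 (10.2-fold, 3.35 ± 0.13, adjusted p = 4.10e-16), Cidec (3.30 ± 0.12), Adipoq (3.25 ± 0.10), Gpd1 (3.11 ± 0.13) and Cd36 (3.10 ± 0.10) rose most, followed by Scd1 (3.04 ± 0.09), Dgat2 (2.96 ± 0.09) and Mrap (2.93 ± 0.11). Pparg (1.60 ± 0.06), Cebpa (1.40 ± 0.09) and Plin1 (2.84 ± 0.09) rose, as did Lpl (1.29 ± 0.06), Slc2a4 (2.46 ± 0.08), Fasn (0.83 ± 0.09) and Pck1 (2.37 ± 0.10). Angptl4 (0.79 ± 0.10) rose as well, but its call ended after quantile normalization (0.093). The matrix genes Mfap4 (-1.25 ± 0.10, adjusted p = 1.15e-09) and Mgp (-0.91 ± 0.14) fell, with the antiviral gene Bst2 (-1.03 ± 0.15, adjusted p = 1.66e-05). Ecrg4 (-0.92 ± 0.09), Tgfb3 (-0.84 ± 0.08) and Klf4 (-0.84 ± 0.11) were lower. Dlk1 (-0.27 ± 0.06) and Col1a1 (-0.42 ± 0.10) fell by less, and Pdk4 (-0.12 ± 0.07) did not pass.

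Mature adipocyte markers were higher in BP (28 of 30 higher, 28 adjusted over the list alone, adjusted p = 7.04e-52). Oxidative phosphorylation was higher (54 of 57 higher, 56 adjusted over the list alone, adjusted p = 2.75e-45), with Uqcrc2 (1.23 ± 0.05). The TCA cycle was higher (22 of 23 higher, 22 adjusted over the list alone, adjusted p = 1.22e-29), with Pcx (2.43 ± 0.11). PPAR gamma targets were higher (20 of 27 higher, 23 adjusted over the list alone, adjusted p = 6.81e-25). Cholesterol synthesis rose (18 of 21 higher, 18 adjusted over the list alone, adjusted p = 2.37e-17), with Nsdhl (0.95 ± 0.07). Lipid droplet genes, fatty acid synthesis and oxidation, LXR targets, triglyceride synthesis, insulin and glucose handling and adipogenic regulators also shifted up with both settings of camera. The insulin and glucose list lost its call after quantile normalization (adjusted p = 0.102). Thermogenic genes shifted up (6 of 14 higher, 8 adjusted over the list alone, adjusted p = 1.7e-06), with a median of 0.34 that turned to -0.22 after quantile normalization, where the call ended (adjusted p = 0.739). Preadipocyte genes shifted down (13 of 29 lower, 16 adjusted over the list alone, adjusted p = 1.13e-06). Contractile genes shifted down (10 of 22 lower, 12 adjusted over the list alone, adjusted p = 3.39e-05), with Itga11 (-0.59 ± 0.07). Extracellular matrix genes shifted down (14 of 41 lower, 16 adjusted over the list alone, adjusted p = 0.00188), with Eln (-0.77 ± 0.05) and Fbln1 (-0.74 ± 0.05). Ribosomal proteins shifted down (12 of 39 lower, 13 adjusted over the list alone, adjusted p = 3.13e-05). The cell cycle list (15 of 41 higher, 16 adjusted over the list alone, adjusted p = 0.000132), with Ube2c (0.38 ± 0.05), gave adjusted p = 0.0846 with an estimated correlation. The interferon response (9 of 30 lower, 9 adjusted over the list alone, adjusted p = 0.00362) gave adjusted p = 0.474 with an estimated correlation. BP changed 3420 genes, 2070 higher and 1350 lower, against 1883 and 1794 after quantile normalization, and 151 changed at least 2-fold.

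PP was likewise compared with DMSO under its code. Cd36 (9.36-fold, 3.23 ± 0.10, adjusted p = 1.62e-17), Fabp4 (3.21 ± 0.13), Cidec (2.99 ± 0.12) and Adipoq (2.90 ± 0.10) rose most, followed by Aldh1a7 (2.87 ± 0.09), the plasma protein gene Itih4 (2.87 ± 0.14), Gpd1 (2.73 ± 0.13) and Scd1 (2.62 ± 0.09). Cebpa (1.58 ± 0.09), Plin1 (2.54 ± 0.09) and Lpl (1.24 ± 0.06) rose, as did Slc2a4 (2.08 ± 0.08), Fasn (0.92 ± 0.09) and Angptl4 (1.01 ± 0.10). Pparg was 2.82-fold higher. Pck1 (1.31 ± 0.10) was higher too, but turned down after quantile normalization (-0.24). The matrix genes Mfap4 (-2.36 ± 0.10, adjusted p = 7.88e-15), Smoc2 (-1.54 ± 0.10), Mmp3 (-1.45 ± 0.12) and Dpt (-1.23 ± 0.09) fell, as did Mgp (-1.23 ± 0.14) and Col1a1 (-0.89 ± 0.10). Ecrg4 (-1.48 ± 0.09), Tgfb3 (-1.38 ± 0.08), the carboxypeptidase Cpz (-1.25 ± 0.06) and Dlk1 (-0.80 ± 0.06) were lower. Pdk4 (-0.05 ± 0.07) did not pass.

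Mature adipocyte markers were higher in PP (27 of 30 higher, 28 adjusted over the list alone, adjusted p = 2.58e-45). Oxidative phosphorylation rose (56 of 57 higher, 57 adjusted over the list alone, adjusted p = 4.08e-54). PPAR gamma targets rose (22 of 27 higher, 22 adjusted over the list alone, adjusted p = 8.61e-27), with Dbi (1.78 ± 0.07). Cholesterol synthesis rose (19 of 21 higher, 19 adjusted over the list alone, adjusted p = 1.5e-24), with Nsdhl (1.18 ± 0.07) and Fdps (0.97 ± 0.06). Lipid droplet genes rose (17 of 21 higher, 18 adjusted over the list alone, adjusted p = 1.11e-20), with Pnpla2 (2.06 ± 0.10). The Nrf2 list shifted up (11 of 25 higher, 12 adjusted over the list alone, adjusted p = 0.00221), with Cat (0.85 ± 0.05). The TCA cycle, fatty acid oxidation, fatty acid and triglyceride synthesis, LXR targets, adipogenic regulators and insulin and glucose handling also shifted up with both settings of camera. After quantile normalization the insulin and glucose list did not pass (adjusted p = 0.158). Thermogenic genes were higher (8 of 14 higher, 8 adjusted over the list alone, adjusted p = 4.85e-07), with a median of 0.37 that turned to -0.044 after quantile normalization, where the call ended (adjusted p = 0.731). Extracellular matrix genes fell (22 of 41 lower, 23 adjusted over the list alone, adjusted p = 4.24e-11), with Postn (-0.92 ± 0.09). Contractile genes fell (12 of 22 lower, 13 adjusted over the list alone, adjusted p = 5.4e-09). Preadipocyte genes shifted down (12 of 29 lower, 16 adjusted over the list alone, adjusted p = 4.49e-07). The cell cycle list shifted down (16 of 41 lower, 19 adjusted over the list alone, adjusted p = 9.45e-07), with Mcm2 (-0.49 ± 0.07). Endoplasmic reticulum stress (9 of 32 lower, 9 adjusted over the list alone, adjusted p = 0.0266), with Trib3 (-1.06 ± 0.07) and Ddit3 (-0.57 ± 0.06), gave adjusted p = 0.0925 with an estimated correlation, and the call ended without PP replicate 2 (adjusted p = 0.114). The interferon response (5 of 30 lower, 5 adjusted over the list alone, adjusted p = 0.00689) gave adjusted p = 0.552 with an estimated correlation. Inflammatory mediators (10 of 29 lower, 11 adjusted over the list alone, adjusted p = 0.0217) gave adjusted p = 0.0947 with an estimated correlation. PP changed 3329 genes, 1969 higher and 1360 lower, against 1825 and 1657 after quantile normalization, and 178 changed at least 2-fold.

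EB, the remaining code, moved genes by small amounts. Fabp4 (1.82-fold, 0.86 ± 0.13, adjusted p = 3.18e-03) rose and its call ended after quantile normalization (0.51). Eln (-0.41 ± 0.05, adjusted p = 1.72e-04), which encodes the elastic fibre protein, and Nr4a1 (-0.40 ± 0.06, adjusted p = 3.18e-03) fell, as did the glutathione-degrading enzyme Chac1 (-0.43 ± 0.07) and Smim31 (-0.47 ± 0.08). These 4 calls held without each replicate in turn. The calls of Cd36 (0.52 ± 0.10) and Ces1d (0.53 ± 0.10) ended without DMSO replicate 1 or 2, that of Cd36 also without EB replicate 3. Those of Scd1 (0.50 ± 0.09) and Lpl (0.36 ± 0.06) ended without DMSO replicate 2. Adipoq (0.34 ± 0.10), Pparg (0.13 ± 0.06) and Cebpa (-0.02 ± 0.09) did not pass. EB changed 115 genes, 76 higher and 39 lower, against 6 and 19 after quantile normalization, with 2054 at unadjusted p under 0.05 in limma. With only EB and DMSO in the limma fit, none of these calls held. The count was 308 without EB replicate 2, 56 without EB replicate 3, 25 without DMSO replicate 1 and 8 without DMSO replicate 2.

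Cholesterol synthesis shifted up in EB (5 of 21 higher, 10 adjusted over the list alone, adjusted p = 1.28e-12), with adjusted p = 0.00318 with an estimated correlation, and Idi1 (0.40 ± 0.07, adjusted p = 1.07e-02) with it. The call of Idi1 ended after quantile normalization (0.24). No other list passed with an estimated correlation. Mature adipocyte markers (4 of 30 higher, 16 adjusted over the list alone, adjusted p = 1.24e-12) gave adjusted p = 0.0701 with an estimated correlation. PPAR gamma targets (4 of 27 higher, 9 adjusted over the list alone, adjusted p = 4.24e-08) gave adjusted p = 0.0897 with an estimated correlation. Lipid droplet genes (1 of 21 higher, 8 adjusted over the list alone, adjusted p = 4.27e-07) gave adjusted p = 0.0701 with an estimated correlation. The TCA cycle (1 of 23 higher, 8 adjusted over the list alone, adjusted p = 7.69e-08) gave adjusted p = 0.0576 with an estimated correlation. Fatty acid synthesis (2 of 24 higher, 8 adjusted over the list alone, adjusted p = 7.58e-07) gave adjusted p = 0.0812 with an estimated correlation. Triglyceride synthesis (1 of 18 higher, 5 adjusted over the list alone, adjusted p = 0.000236) gave adjusted p = 0.0576 with an estimated correlation. Fatty acid oxidation (4 of 31 higher, 5 adjusted over the list alone, adjusted p = 2.02e-05) gave adjusted p = 0.0861 with an estimated correlation. LXR targets (2 of 14 higher, 2 adjusted over the list alone, adjusted p = 0.00144) gave adjusted p = 0.127 with an estimated correlation. Oxidative phosphorylation (2 of 57 higher, 8 adjusted over the list alone, adjusted p = 0.0025) gave adjusted p = 0.389 with an estimated correlation. Thermogenic genes (0 of 14 higher, 2 adjusted over the list alone, adjusted p = 0.0025) gave adjusted p = 0.251 with an estimated correlation. Insulin and glucose handling (0 of 33 higher, 8 adjusted over the list alone, adjusted p = 0.0223) gave adjusted p = 0.185 with an estimated correlation. The cell cycle list (1 of 41 lower, 1 adjusted over the list alone, adjusted p = 0.000655) gave adjusted p = 0.183 with an estimated correlation. Preadipocyte genes (0 of 29 lower, 0 adjusted over the list alone, adjusted p = 0.02) gave adjusted p = 0.0576 with an estimated correlation. After quantile normalization the calls of mature adipocyte markers (adjusted p = 0.89), PPAR gamma targets (0.621), lipid droplet genes (0.355) and oxidative phosphorylation (0.621) ended. Those of triglyceride synthesis, fatty acid oxidation, LXR targets, thermogenic genes and insulin and glucose handling ended too. Without DMSO replicate 2 the calls of thermogenic genes (adjusted p = 0.349), LXR targets (0.136), insulin and glucose handling (0.177) and preadipocyte genes (0.158) ended. The insulin and glucose list also did not pass without EB replicate 1 or DMSO replicate 1, nor preadipocyte genes without EB replicate 1.

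**Figure D1:**
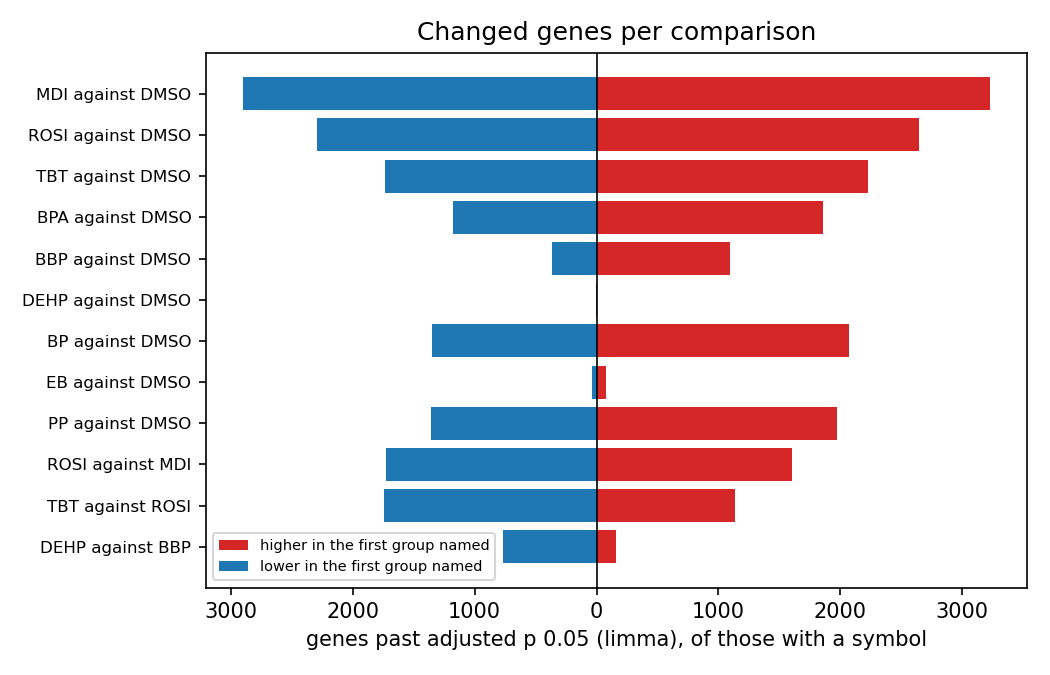
Genes past an adjusted p of 0.05 (limma) in each comparison, of 14763 named genes; bars to the right count genes higher in the first group named and bars to the left genes lower in it. MDI changed 6126 genes and DEHP 2.

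The agents were ranked by the mean of the 30 mature adipocyte markers per array, log2 sample over reference. The level was -1.86 ± 0.18 in DMSO (SD, n = 3) and 1.11 ± 0.02 in MDI. ROSI reached 0.53 ± 0.07, TBT 0.03 ± 0.06, BP 0.00 ± 0.02, PP -0.23 ± 0.03, BBP -0.53 ± 0.04, BPA -0.76 ± 0.05, EB -1.61 ± 0.09 and DEHP -1.77 ± 0.03. A two-sided exact permutation test against DMSO gave p = 0.1, the smallest that 3 arrays against 3 allow, for each agent except DEHP (p = 0.6). The difference from DMSO in the adipocyte marker level shrank after quantile normalization, from 2.96 to 1.79 for MDI, 2.38 to 1.52 for ROSI, 1.89 to 1.12 for TBT and 1.86 to 1.11 for BP. It went from 1.62 to 0.83 for PP, 1.33 to 0.45 for BBP, 1.09 to 0.33 for BPA, 0.25 to 0.014 for EB and 0.09 to -0.015 for DEHP, which kept the order. The shrinkage can come from that step itself. It forces the wide DMSO arrays (SD of log ratios 0.244 to 0.295) and narrower ones such as BP (0.151 to 0.204) onto the same distribution. Differences between agents were not tested on this level. The direct contrasts given above tested the fold changes of the list with camera, not the level per array.

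**Figure D2:**
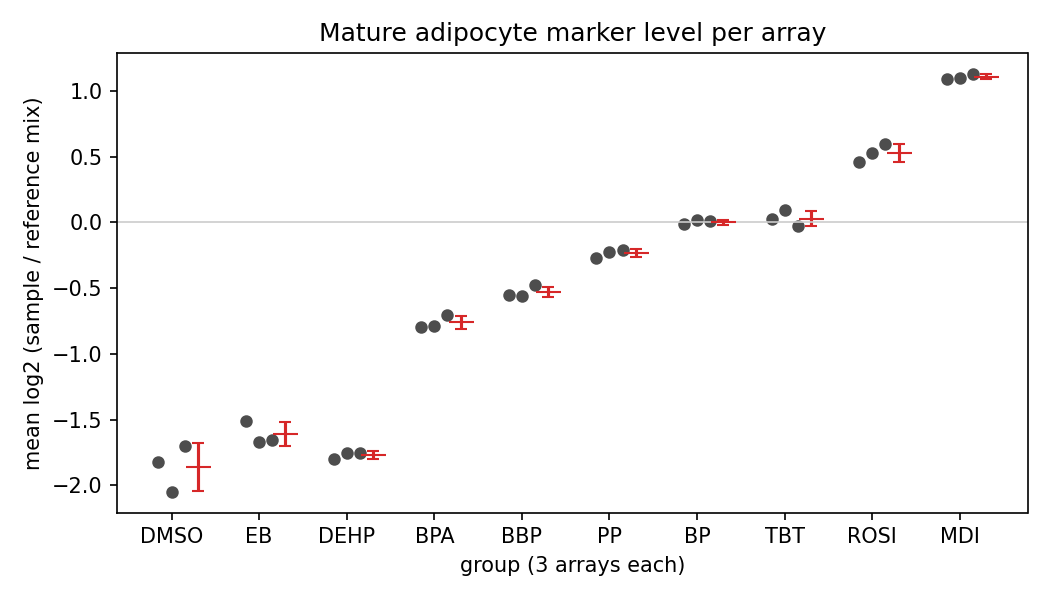
Mean log2 (sample over reference) of the 30 measured mature adipocyte markers on each array, by group; dots are the 3 arrays of a group and red bars their mean and SD. DMSO lay at -1.86 and MDI at 1.11.

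Fold changes against DMSO were set beside each other across genes, which are not independent replicates. Pearson's r with MDI was 0.839 for ROSI, 0.819 for BP, 0.801 for TBT, 0.793 for PP, 0.71 for BBP, 0.674 for BPA, 0.332 for EB and 0.213 for DEHP. Because all share the same 3 controls, simulated groups without any effect gave a mean r of 0.504 and a covariance of 0.00376 over 100 draws. After quantile normalization, for which no groups without effect were simulated, r with MDI was 0.523 for BPA and 0.407 for BBP. The r values of EB and DEHP lay under the simulated mean. That mean is for pairs without any effect, so it is no baseline for r with MDI, which changed many genes. By covariance with MDI, EB and DEHP lay above the simulated 0.00376. The draws took genes as independent, each with an SD pooled over all groups. The adipocyte marker level, however, varied more in DMSO (SD 0.18) than in any other group (0.09 at most, in EB). The simulated covariance may thus be too low, and the excess of EB and DEHP does not show a response shared with MDI. The observed covariances with MDI were 0.143 for ROSI, 0.111 for TBT, 0.0972 for BP, 0.0165 for EB and 0.00991 for DEHP. BP and PP had the highest r of any pair (0.882), with 1520 genes higher in both against 276.1 for independent lists and 873 lower in both against 124.4. MDI and ROSI shared 2214 higher genes against 579 and 1667 lower genes against 450.1. In all 7 agents other than DEHP and EB, 698 genes were higher and 142 lower, while 487 genes were called in opposite directions by different agents. Since 3 controls cannot be split into separate sets of at least 2 arrays, part of the excess may come from the shared controls.

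**Figure D3:**
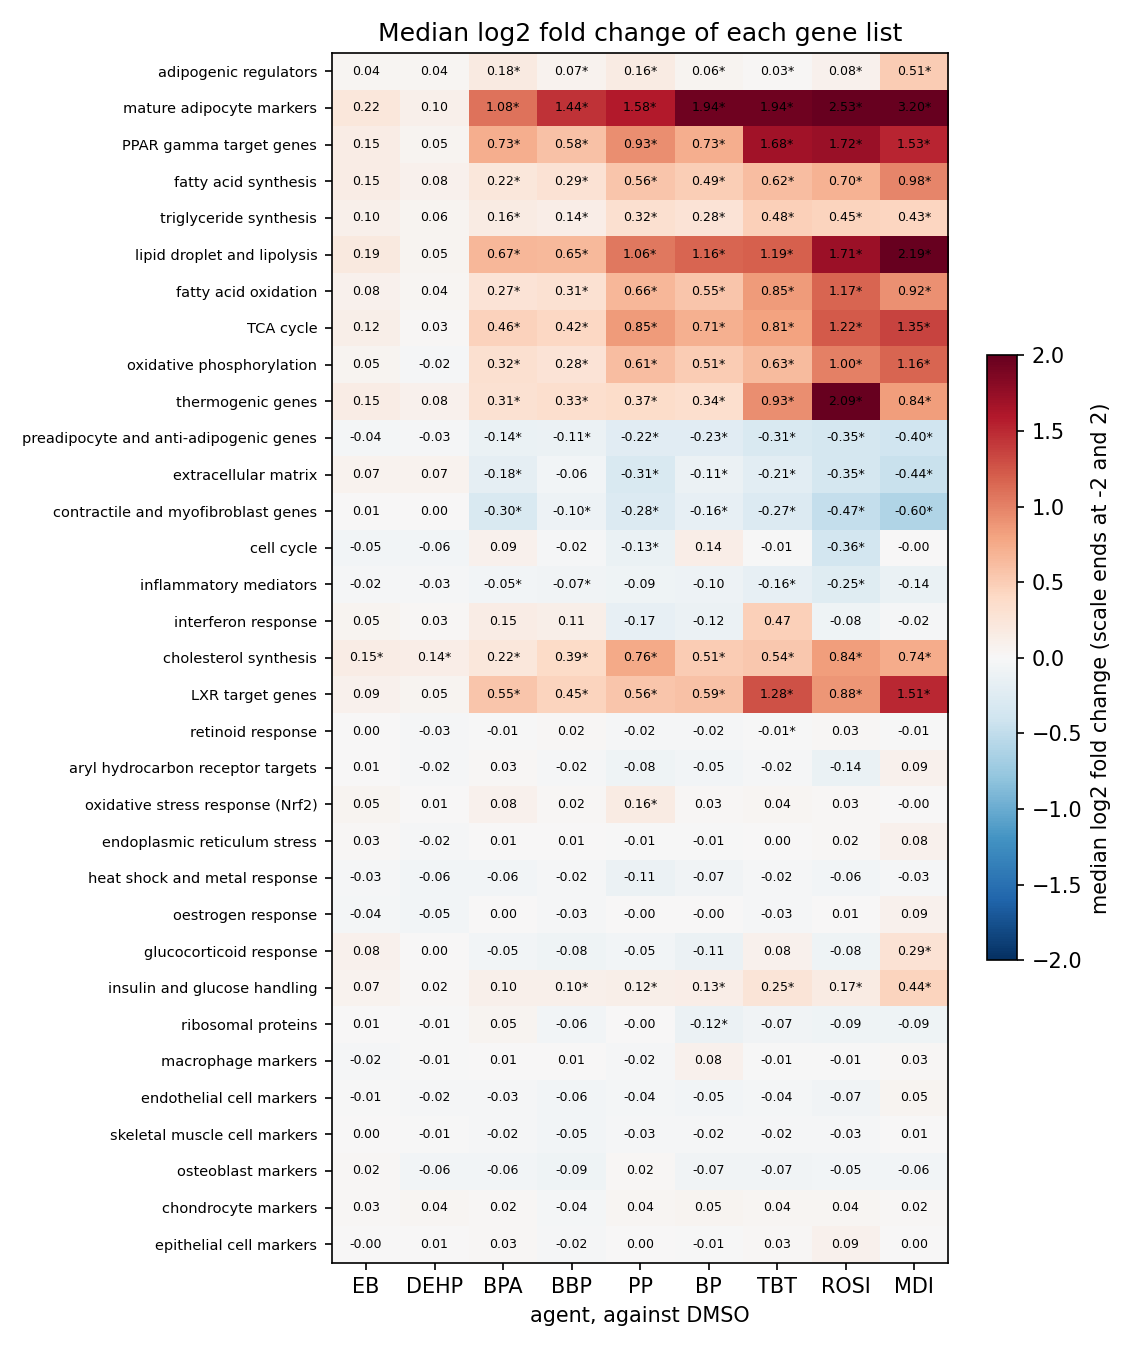
Median log2 fold change against DMSO of the measured genes of 33 gene lists (down) for 9 agents (across), with a star where limma's camera gave an adjusted p under 0.05 with both the preset and the estimated correlation. The mature adipocyte markers ran from 0.10 in DEHP to 3.20 in MDI; after quantile normalization the median of the thermogenic genes turned negative in BPA, BBP, BP and PP, and that of the mature adipocyte markers in DEHP.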

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

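With 3 arrays per group, a shared DMSO control and deposited ratios whose normalization is not stated, the counts of agents with small changes depended on how the data were handled. Some alternatives were added after the data were seen: the adipocyte level, the gene lists under quantile normalization and the list medians. Of 1613 results for named genes, 125 lost a call without some replicate. After quantile normalization 25 with a call before or after that step turned direction, as did 22 without one. A further 136 kept their direction but lost their call then, and 106 did so with only the compared groups in the fit.

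A fold limit of 1 on the log2 scale lowered the counts by its construction. It left 603 genes for MDI, 389 for ROSI, 217 for TBT, 74 for BPA, 58 for BBP, 151 for BP and 178 for PP. For DEHP and EB limma then left 0 each, of 1676 and 2054 at unadjusted p under 0.05. The direct contrasts kept 136 for ROSI against MDI, 43 for TBT against ROSI and 42 for DEHP against BBP.

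Quantile normalization between arrays gave 947 genes for BBP, 11 for DEHP, 25 for EB and 468 for DEHP against BBP. It forces arrays with a wide spread of log ratios, such as DMSO and MDI (SD 0.244 to 0.333), onto the same distribution as narrower ones such as BP replicate 2 (0.151). A lost call or a turned direction after this step is therefore no evidence by itself that a change was absent. Genes with a call before or after this step that turned negative were Hp in ROSI (-0.17), Fasn (-0.11), Cox7a1 (-0.15), Hp (-0.17) and Pmvk (-0.057) in BPA. In BBP they were Angptl4 (-0.58), Cox7a1 (-0.37), Slc36a2 (-0.0044), Hp (-0.48) and Hsd11b1 (-0.52). In BP they were Cox7a1 (-0.27), Apoc1 (-0.093) and Alpl (-0.021), and in PP Pck1 (-0.24), Cox7a1 (-0.03) and Hp (-0.20). Such genes that turned positive in ROSI against MDI were Suclg1 (0.0048) and Pmvk (0.12). In DEHP against BBP they were Angptl4 (0.55), Idh3a (0.14), Cox7a1 (0.41), Slc36a2 (0.027), Hp (0.48), Cbr3 (0.022) and Hsd11b1 (0.49).

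Under quantile normalization the correlation with MDI across genes was 0.698 for TBT, 0.523 for BPA, 0.407 for BBP, 0.683 for BP, 0.219 for EB and 0.651 for PP. The adipocyte marker level minus DMSO was 1.79 for MDI, 1.52 for ROSI, 1.12 for TBT, 1.11 for BP, 0.83 for PP, 0.45 for BBP, 0.33 for BPA and 0.014 for EB. Under it 5 gene lists shifted for EB. Calls gained under it were glucocorticoid response, down, for BPA (adjusted p = 0.0254) and BBP (0.000576), and inflammatory mediators, down, for DEHP (0.0337), from limma's camera.

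Array weights gave 31 genes for DEHP and 69 for EB. With only the compared groups in the fit, limma gave 892 for BBP and 0 for DEHP and for EB, against 1676 and 2054 at unadjusted p under 0.05 in the full fit. With each probe on its own, 1 gene passed for DEHP. The cause of these moves was not tested. With an estimated correlation, camera left 1 list for DEHP and 1 for EB.

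With the replicate block, 13 genes passed for DEHP, where the numbers do not pair. Pairing by number was seen in the data for PP only, and there the block ended the call of Aldh3a1 (-0.15) and changed no other call of a named gene or list. For BP each sample also correlated best with the DMSO sample of its own number (0.0387, 0.0968 and 0.121), a hint from the data alone. The block brought in heat shock for BPA (adjusted p = 0.048, limma) and glucocorticoid response for EB (adjusted p = 0.0417, limma).

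Without single replicates the counts ran from 814 (without DMSO replicate 2) to 1559 (without DMSO replicate 3) for BBP and from 1 (without DEHP replicate 3) to 37 (without DMSO replicate 3) for DEHP. For EB they ran from 8 (without DMSO replicate 2) to 308 (without EB replicate 2), and for DEHP against BBP from 595 (without BBP replicate 3) to 811. The lists for DEHP ran from 2 (without DEHP replicate 2) to 10 (without DMSO replicate 3).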

Other observations

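Chosen after the result was seen were the test of further conversion under ROSI and TBT, the test on Fabp3 and Pdk4, the test of a low level on all 3 DMSO arrays, and the contrast of TBT with MDI. The other tests had their predictions written first.

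Of the interferon response genes, 20 of 30 were called higher in TBT than in DMSO, while the list gave adjusted p = 0.187 with an estimated correlation. One cause might be a single TBT array, but without each of the TBT arrays in turn the number of members called higher was at least 17, which speaks against it. Another might be that this list varies between arrays of a group anyway. The difference of the list mean was 0.55, above the largest range within a group (0.46, in EB) but by less than the SD of TBT (0.17), and the rule for reading this test was tightened after the values were seen, so the question stays open. In EB, camera with the preset correlation called this list up without replicate 1 (adjusted p = 0.00637) or 2 (0.0162) and down without replicate 3 (0.0441). In ROSI it called the list down without ROSI replicate 1 (0.0434). With all arrays the list passed in neither (0.213 in EB and 0.376 in ROSI). Interferon beta assayed in the medium of TBT and DMSO cells, each in several cultures grown apart, could help to tell a TBT effect from such spread.

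At least 2-fold higher than in MDI were 28 genes in ROSI and 39 in TBT, with 12 in both, a number to which the shared MDI arrays add: Fabp3, Ccl8, Pdk4, 3300005D01Rik, Dpp7, Mlana, Cyp26b1, Col8a1, Pmepa1, Ccl2, Ccn1 and Myo5a. Further conversion to fat cells is not a likely cause, since the adipocyte marker level differed from that in MDI by -0.58 in ROSI and -1.07 in TBT, nor is a single MDI array, since at least 9 of the 12 kept the pattern without each of them in turn. For the set as a whole a low level in MDI alone may be the cause, as the median change against DMSO was -0.03 in ROSI and -1.42 in MDI. Not all of the 12 follow that median: Fabp3 and Pdk4, known PPAR targets picked from the 12 after their values were seen, had a smallest rise of 1.62 in ROSI or TBT against DMSO, beside a lowest change of -0.17 in MDI. Cyp26b1 also lay above DMSO in TBT (2.40) and in ROSI (0.63), beside -0.70 in MDI, and Ccl8 in ROSI (0.81), beside -1.71 in MDI.

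Cholesterol synthesis genes shifted up in DEHP and EB, in which limma called 2 and 115 genes. In each this was the only list that passed with both settings of camera. A single DMSO array is not a likely cause, since the highest adjusted camera p without any 1 of them was 1.29e-08. A low level on all 3 DMSO arrays could give the same shift, because the list was up against DMSO in 9 of 9 agents, and these data do not separate the causes. Untreated cells next to DMSO cells on new arrays would do so.

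For each comparison the 6 arrays were split in all 10 ways into 3 against 3, and only the real split, 1 of 10, reached its count. Splits of 3 against 3 are too few for a share under 0.05. A mixed split also puts any real difference between the groups into the spread within them. Where many genes differ, its count is thus low by construction, so these counts are no measure of chance. The highest count of another split was 0 against 6126 for MDI, 1 against 4941 for ROSI, 1 against 3958 for TBT and 2 against 3031 for BPA. It was 0 against 1460 for BBP, 0 against 2 for DEHP, 1 against 3420 for BP, 14 against 115 for EB and 1 against 3329 for PP. For ROSI against MDI it was 1 against 3332, for TBT against ROSI 1 against 2880 and for DEHP against BBP 2 against 928.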
